A study of Mus musculus with 24 samples.

How the data were processed

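The tissue was the amygdala of adult male mice of the strains BL6 and DBA, taken at 10 to 16 weeks, with about 2 animals pooled per library. Per the labels, nuclei for RNA were sorted to a mix of 75% neurons and 25% other cells with the neuronal antibody NeuN, and nuclei for ATAC were sorted on a DNA dye alone. Of 24 samples in the series, 4 RNA and 4 ATAC libraries were used. The other 16, methylation libraries of 8 strains, were not analysed here. The deposited RNA values are counts of unique molecules per gene that the authors summed over the nuclei of each cell type and library. The deposited ATAC values are counts per peak, summed by the authors in the same way, and the deposited numbers of nuclei are counts too. The submitters' processing notes name Cell Ranger 6.0.2 and Seurat 4.0.5 for RNA, Cell Ranger ATAC 2.0.0 for ATAC, and the genome build mm10. The notes do not state filters on nuclei, how doublets were treated, the gene annotation of each strain, the peak caller, or whether fragments or insertion sites were counted, so an ATAC count is not known to be 1 fragment. Doublets were not sought here, since the counts are sums over nuclei. Cell type names are the authors' own. The tables number libraries 2 and 3 and the titles 1 and 2 in each strain, so libraries are named by the tables.

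RNA libraries held 30693600 to 66304400 counts and ATAC libraries 66535400 to 86927900. A cell type was tested when each of its 4 columns had 10 or more nuclei and at least 50000 RNA counts or 100000 ATAC counts, which left 20 of 22 types for RNA and 16 for ATAC. Exc-Strip2, with 75, 3, 1 and 77 RNA nuclei, and NN-Endo-SMC-Peri were left out for RNA. Counts of cell types were also summed over all nuclei and over the excitatory, inhibitory and non-neuronal classes. Differences are DBA minus BL6. Each was tested with edgeR 4.0.16 by its robust quasi-likelihood test after TMM scaling and filterByExpr with its minimum count of 10, with 2 libraries per strain, and Benjamini-Hochberg adjustment over all features of that test. A feature with adjusted p under 0.05 was called. Interactions between strain and class used the summed classes with each library as a block. Counted in both strains means 10 or more counts in each strain over all nuclei, which held for 22155 genes; this restriction was chosen after the gene sets of the strains were seen to differ. Folds against a strain at 0 used a floor of 3 counts over the strain and cover counting error only, as do the intervals.

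The comparisons, the rule for named genes, 36 gene lists and the alternatives were fixed before the data were examined. The rule took, for RNA, the 8 genes called higher and the 8 called lower in the most cell types, with ties going to the larger mean change. It took the 3 called genes each way with the largest change in each class sum at a mean log2 CPM of 5 or more. It took up to 4 members per list with the smallest p in the unit with the most called members, 4 called genes each way per interaction, and every measured strain variant. For ATAC it took the 5 peaks each way called in the most types and called peaks at the ends of the named genes. Genes with provisional symbols were passed over, and a few genes that the rule took are not reported here. The same rule was run on genes counted in both strains, and those values come from that restricted test. Genes named for RNA and accessibility together were chosen after their values were seen. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 in 9 units, all nuclei, both neuronal classes and 6 non-neuronal types, and again with an estimated correlation. With 2 libraries per strain, an estimated correlation leaves few degrees of freedom. That setting could therefore hardly call any list and cannot decide against one. The lists covered ribosomal proteins, the mitochondrial genome, heat shock, immediate early genes, myelin, cholesterol synthesis, interferon response, MHC class I, the circadian clock, DNA methylation, synapses, receptors, channels, neuropeptides, Zfp genes, protocadherins, known strain variants and markers of 14 cell types. Coordinates came from RefSeq on mm10. That table held no strand, so the planned window at the transcription start was replaced by peaks within 2 kb of either end of a gene, or 10 kb as an alternative. Same direction of RNA and ATAC was tested by Fisher's exact test, two-sided.

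Alternatives were RLE factors, total counts alone, no filter, DESeq2 1.42.0, each library left out in turn, the library number as a block, a 1.5-fold threshold, a shared dispersion, higher minimum counts per cell type and columns thinned to equal depth. After the data were seen, genes counted in both strains and a block that crosses the library numbers were added. Each comparison was tested on simulated data with 200 changed features. In single RNA types 4.48% to 74.6% of 2-fold changes and 53.0% to 98.5% of 4-fold changes were recovered, and false calls were 1.54% to 17.4% of calls. Over all RNA nuclei these were 44.8%, 89.4% and 15.0%, for the non-neuronal interaction 50.7%, 74.2% and 23.8%, and for the inhibitory interaction 53.7%, 89.4% and 15.6%. In ATAC types 14.9% to 44.8% and 68.2% to 87.9% were recovered with at most 12.0% false, and over all ATAC nuclei 65.7% and 98.5% with 10.6% false. The ATAC interaction recovered 0% and 1.52%. A list moved in simulated data was called by camera (adjusted p = 2.95e-41) and 0 of 20 random lists were. Genes were simulated independently of each other, so this does not show how often lists of correlated genes are falsely called. Work was done in R 4.3.3 with the package data.table (1.17.8), and figures in Python 3.11.15 with matplotlib 3.10.9.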

Results

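Nuclei of the amygdala of adult male mice were profiled in 2 inbred strains named BL6 and DBA. Single-nucleus RNA sequencing counted transcripts per gene, and single-nucleus ATAC sequencing counted open chromatin per peak. Each strain had 2 libraries per assay, each made from the pooled tissue of about 2 animals aged 10 to 16 weeks. The RNA libraries held 66304400 and 30693600 counts in BL6, from 8079 and 4426 nuclei, and 32133800 and 50637100 counts in DBA, from 2867 and 6276 nuclei. The ATAC libraries held 72453800 and 86927900 counts in BL6, from 3941 and 6943 nuclei, and 80428900 and 66535400 counts in DBA, from 3694 and 4541 nuclei. The deposited counts were summed by the authors over 22 cell types and covered 34039 genes and 271433 peaks. The libraries are called library 2 and library 3 of each strain, after the numbers in the count tables. Values per strain are means ± SD over n = 2 libraries, in CPM, counts scaled to a total of 1000000.

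Several cell type names went with well-known marker transcripts, but NN-Endo-VLMC had no counts of the endothelial markers Cldn5 and Flt1. Myelin genes were highest in oligodendrocytes (NN-ODC), where Mbp reached 4547 ± 120.1 CPM and Mog 1058 ± 44.2 CPM over the 4 libraries. The microglial receptor Csf1r reached 1209 ± 122 CPM in NN-MGC, the neuropeptide Sst 1045 ± 173 CPM in Inh-Sst, and the vesicular glutamate transporter Slc17a7 317 ± 42.2 CPM in Exc-Tafa1. Foxp2, a transcription factor of intercalated cells, was at 1529 ± 88.1 CPM in Inh-Tshz1 and nearly as high, at 1504.5 CPM, in NN-Endo-VLMC. Neurons made up 55.2 ± 11.6% of RNA nuclei in BL6 and 62.0 ± 11.2% in DBA, a difference smaller than the spread between libraries. In ATAC, which the labels say was sorted without the neuronal antibody NeuN, neurons made up 97.8 ± 0.283% of nuclei in BL6 and 97.6 ± 0.820% in DBA. In RNA, oligodendrocytes made up 9.81 ± 0.469% of nuclei in BL6 and 6.20 ± 2.28% in DBA, microglia 6.48 ± 1.002% and 4.52 ± 1.94%, and the unnamed neuronal type Neuronal-Aldoa-Cst3 3.004 ± 0.449% and 0.972 ± 0.451%. With 2 libraries against 2, the smallest two-sided p that an exact permutation test of these shares can reach is 0.333, so none could pass 0.05.

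The first comparison asked which genes differed in RNA level between DBA and BL6, in each cell type and over all nuclei. Among genes counted in both strains, the scavenger receptor gene Stab2 (mm10 chromosome 10, 86841194 to 87008038) rose from 5.28 ± 1.096 CPM in BL6 to 211 ± 16.9 CPM in DBA over all nuclei. Atp5o, a subunit of the mitochondrial ATP synthase (chromosome 16, 91925223 to 91931630), rose from 29.9 ± 0.986 to 443 ± 1.09 CPM. Cox16, an assembly factor of cytochrome c oxidase (chromosome 12, 81358852 to 81485137), fell from 248 ± 10.8 to 7.90 ± 0.397 CPM. Schip1 (chromosome 3, 68064802 to 68626482) fell from 796 ± 22.7 to 26.7 ± 3.61 CPM. Stab2 was called higher in 20 of 20 cell types tested and Atp5o in 19, while Cox16 was called lower in 20 and Schip1 in 19. Both DBA libraries lay beyond both BL6 libraries for each of these genes, with log2 fold changes of 5.39 (adjusted p = 1.69e-05), 3.94 (1.69e-05), -4.93 (1.69e-05) and -4.85 (1.69e-05).

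Other genes counted in both strains were called in most cell types. Rnf121, a ubiquitin ligase of the endoplasmic reticulum, rose from 42.2 ± 1.29 to 405 ± 38.8 CPM, and Mlycd, which degrades malonyl-CoA, from 9.69 ± 0.901 to 76.5 ± 6.43 CPM. Zfp949 rose from 36.1 ± 0.406 to 106 ± 8.68 CPM and Cfap54, a gene of cilia and flagella, from 60.6 ± 7.10 to 209 ± 12.2 CPM. Sfi1, a centrosomal protein gene, went from 53.8 ± 14.3 to 406 ± 21.6 CPM and Pisd from 35.1 ± 7.47 to 233 ± 3.05 CPM, but copies of these 2 genes stand elsewhere in the genome under names such as Pisd-ps1, so their values are uncertain. Umad1 fell from 104 ± 5.43 to 5.57 ± 0.478 CPM and Glcci1 from 62.3 ± 3.34 to 2.27 ± 0.172 CPM. Transcripts of the mitochondrial genome were lower as well, with mt-Co2 at 709 ± 170 CPM in BL6 and 0.391 ± 0.201 CPM in DBA. In the DBA libraries mt-Co2 had 8 and 27 counts. Being counted in both strains does not exclude different gene models per strain, for these transcripts or for the genes named above.

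Summed over the 20 cell types, 12183 calls were made on genes counted in both strains, 4586 higher in DBA and 7597 lower, at adjusted p under 0.05. With every gene of the table the sum was 28655, 18041 higher and 10614 lower, from 113 in NN-VLMC to 3394 in Exc-Vwa5b1. The share of calls higher in DBA was thus 37.6% on genes counted in both strains and 63.0% on all genes, and DESeq2 on all genes called 18013 higher and 5285 lower, 77.3% higher. Over all nuclei, 1033 genes counted in both strains were called, 361 higher and 672 lower, against 6073 of 25329 with every gene of the table. Of the 4230 genes counted in both strains and called in any type, 2152 were called in 1 type and 71 in 15 or more, and 86.4% of the 2078 called in 2 or more types went in 1 direction. Scaling by total counts alone shifted the median gene by -0.13 in NN-Astro and -0.15 in NN-ODC on the log2 scale.

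**Figure D1:**
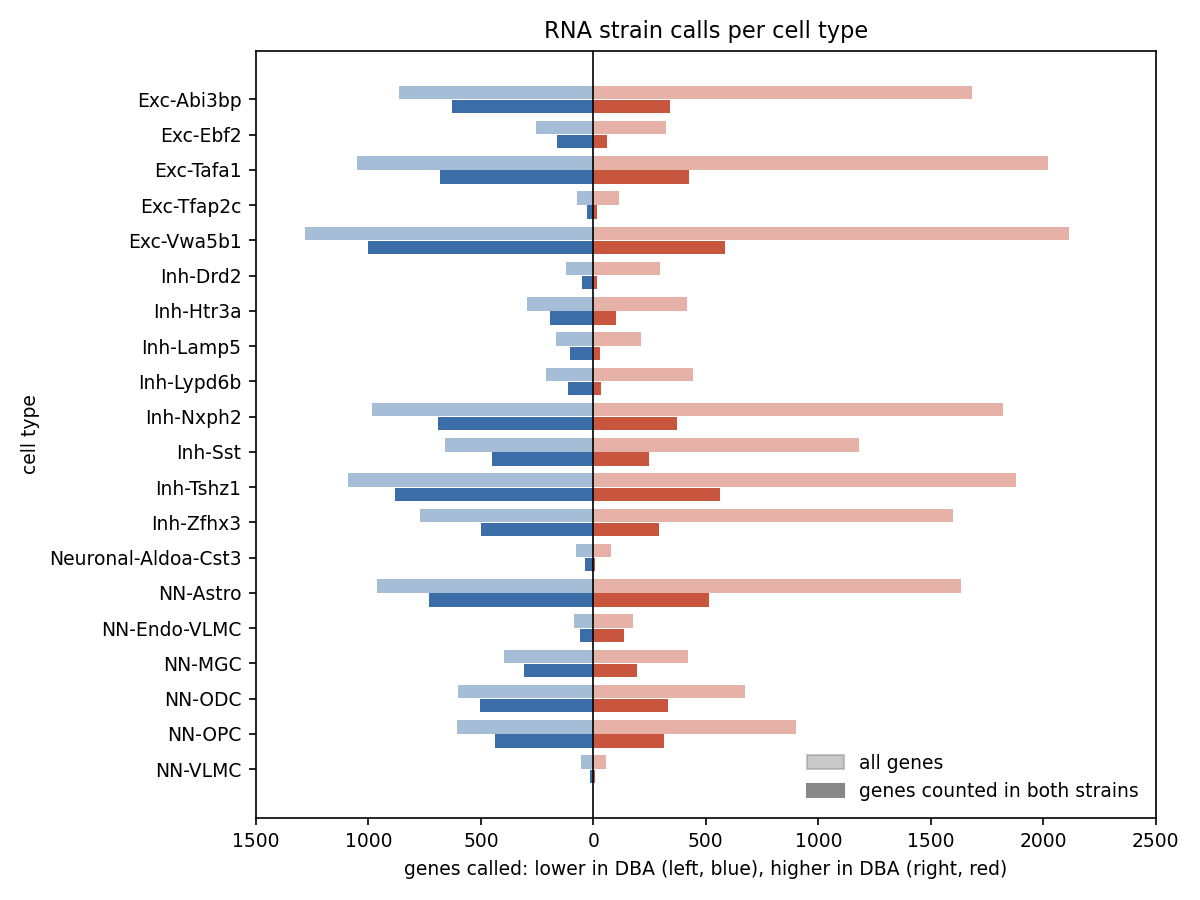
Number of genes called higher in DBA (red, to the right) and lower in DBA (blue, to the left) in each cell type at adjusted p under 0.05, from 2 libraries per strain. Lighter bars count every gene of the table and darker bars genes counted in both strains, where lower calls outnumber higher ones, 7597 against 4586 over the 20 types.

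Many genes were counted in 1 strain alone. CT010467.1 was at least 136663-fold higher in DBA, Galnt2l at least 61582-fold and Pisd-ps2 at least 7329-fold. AY036118 was at least 37649-fold lower in DBA and BC005561 at least 3468-fold lower. Several such genes were older and newer symbols of the same gene. March1 had 898 and 790 CPM in the BL6 libraries and none in DBA, while Marchf1, its newer symbol, had 805 and 845 CPM in DBA and none in BL6. Sept7, Septin7, Marchf6 and Marchf7 were likewise counted in 1 strain each, at least 4357-fold lower in DBA for Sept7 and at least 4401-fold higher for Septin7. Atp5f1 was at least 1417-fold lower, but under its newer symbol Atp5pb the gene was at 44.5 CPM in DBA, against 51.4 CPM as Atp5f1 in BL6. Thoc2l was at least 8485-fold higher, at 262 CPM in DBA, against 21.8 CPM in BL6 under its older symbol D930016D06Rik. These CPM come from the summed libraries of a strain. Mir6236 was at least 20109-fold higher. In all, 7903 genes had counts in DBA alone and 1294 in BL6 alone, and these genes took 0.887% and 0.914% of counts in the BL6 libraries and up to 3.37% in the DBA libraries. Of 126 pairs of older and newer symbols, 68 had 100 or more counts under each name, and 60 of these lay within 1.5-fold once the names were joined. The 2 strains were thus counted under different names for these genes, and no fold change of a gene counted in 1 strain is read as a change in its transcription. Folds against 0 use a floor of 3 counts over the group.

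**Figure D2:**
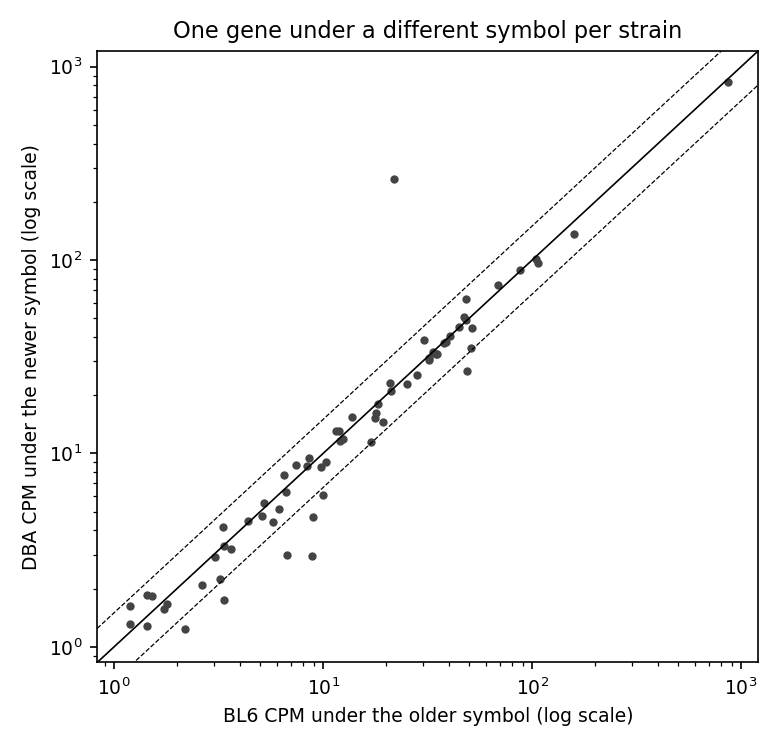
CPM of the older symbol in BL6 against the newer symbol of the same gene in DBA for 68 pairs with 100 or more counts under each name. Values come from the summed counts of 2 libraries per strain and are on log axes. The solid line marks equality and the dashed lines 1.5-fold, and 60 of the 68 pairs lie between the dashed lines.

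When nuclei were summed by class, Stab2 and Atp5o were again among the genes with the largest rises. In excitatory neurons Stab2 rose from 5.44 ± 0.601 to 222.5 ± 18.5 CPM (log2 fold change 5.41, adjusted p = 7.55e-12), Atp5o from 23.4 ± 1.85 to 391 ± 4.70 CPM and Rnf121 from 44.0 ± 1.84 to 456 ± 13.1 CPM. In inhibitory neurons Stab2 rose by 5.32, Atp5o by 3.92 and Rnf121 by 3.05 on the log2 scale, and in non-neuronal nuclei Stab2 rose by 5.62, Atp5o by 4.06 and Sfi1, with its near-identical copies, by 3.90. The transcripts mt-Co2, mt-Co3 and mt-Atp6 had the largest falls in all 3 classes among genes counted in both strains at a mean log2 CPM of 5 or more, with log2 fold changes of -10.48, -8.01 and -6.87 in excitatory neurons. Among genes of 1 strain, CT010467.1, Galnt2l, Marchf1 and mt-Rnr2 led the higher ones, at least 43349-fold for CT010467.1 in excitatory neurons, and March1, AY036118 and AC149090.1 the lower ones. The excitatory call of AC149090.1 was lost without DBA library 3 (adjusted p = 0.0671). Genes counted in both strains gave 1754 calls in excitatory neurons, 640 higher and 1114 lower, 1583 in inhibitory neurons, 595 and 988, and 1416 in non-neuronal nuclei, 564 and 852. With every gene the counts were 5065, 5092 and 3825, and higher calls outnumbered lower ones, at 3491 and 1574, 3636 and 1456, and 2582 and 1243.

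Of 17 genes listed as known variants between these strains, Alad was the one called over all nuclei. Alad, an enzyme of heme synthesis (chromosome 4, 62505984 to 62520063), rose from 5.86 ± 0.00892 to 16.4 ± 0.309 CPM (log2 fold change 1.53 ± 0.15 SE, adjusted p = 0.000181, higher in both DBA libraries) and was called in 11 cell types. The GABA-A receptor subunit Gabra2 was at 425 ± 14.5 CPM in BL6 and 326 ± 5.24 CPM in DBA over all nuclei (-0.33, adjusted p = 0.0562) and was called lower in 11 types. In inhibitory neurons Gabra2 fell by 0.36 on the log2 scale (adjusted p = 0.00615, lower in both DBA libraries), a call that ended without DBA library 2 (adjusted p = 0.05002). Nnt, a mitochondrial transhydrogenase, fell in inhibitory neurons from 4.99 ± 1.11 to 2.37 ± 0.610 CPM (log2 fold change -1.04, adjusted p = 0.0161), not called without BL6 library 3 (0.0733) or without DBA library 3 (0.166). Over all nuclei Nnt (-0.68), Gpnmb (-1.28), Cdh23 (-0.49), Hc (-0.30), Fscn2 (-0.24), Ahr (-0.20), Mpdz (-0.05), Glo1 (0.04), Wdfy1 (0.15), Ide (0.16) and Kcnj9 (0.28) did not pass, in log2 fold change, with adjusted p from 0.0946 to 0.946. Klrd1, Tyrp1 and H2-Ea had too few counts to test, and H2-Ea had 42 and 6 counts in the DBA libraries and none in BL6. As a list these variants were called in no unit (smallest adjusted p = 0.564).

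Ribosomal protein genes were lower in DBA in all 9 units tested, that is all nuclei, both neuronal classes and 6 non-neuronal types. Over all nuclei 64 of 82 were called, 62 lower and 2 higher, and 77 adjusted over the list alone, with a median log2 fold change of -0.66 in genes counted in both strains. Rps10 fell from 34.0 ± 3.56 to 4.99 ± 0.284 CPM, Rpl24 from 45.2 ± 1.35 to 6.95 ± 0.931 CPM and Rpl27a from 82.7 ± 8.85 to 20.1 ± 0.238 CPM. The 2 higher members, Rps4l and Rpl32l, were counted in DBA alone, so the genes counted in each strain differed within this list. Different gene models per strain were not tested for the ribosomal falls, or for the heat shock genes that follow, and are not excluded. The list test (camera) gave adjusted p = 2.54e-12 over all nuclei and 3.62e-09 in excitatory neurons, and adjusted p = 0.963 with an estimated correlation. With 2 libraries per strain the estimated correlation could hardly call any list, so its values here and below cannot decide. Of heat shock genes in inhibitory neurons 5 of 11 were called lower and none higher, 6 adjusted over the list alone, with Hspa8 from 115 ± 9.73 to 42.8 ± 1.53 CPM and Dnaja1 from 82.6 ± 7.25 to 57.2 ± 4.55 CPM. Their camera adjusted p was 0.0243, and adjusted p = 0.963 with an estimated correlation; the list was also called lower in NN-MGC (0.0379) and NN-OPC (0.0183). In inhibitory neurons Hspa1a was not called when any 1 library was left out (0.128 to 0.254), nor Hsp90aa1 without DBA library 2 (0.180) or DBA library 3 (0.0616). The 12 mitochondrial mRNAs counted in both strains were lower in DBA over all nuclei, 11 of them called, from mt-Co2 (-10.66) to mt-Nd5 (-1.39), with mt-Atp8 (-0.94) at adjusted p = 0.142. The list of mitochondrial genome transcripts was called lower in 8 of 9 units, with adjusted p = 2.18e-49 in NN-ODC and adjusted p = 0.963 with an estimated correlation. The exception was all nuclei (0.422), where 19 of 32 members were called higher, mt-Rnr1 and mt-Rnr2 among them, and none of the 19 was counted in both strains. With genes counted in both strains the list was called lower in 9 of 9 units.

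Lists of oligodendrocyte and microglial transcripts were called lower in some units. In inhibitory neurons 7 of 15 myelin genes were lower and none higher, 7 adjusted over the list alone, with Mobp from 5.86 ± 0.297 to 1.71 ± 0.261 CPM and Cnp from 24.4 ± 2.46 to 13.7 ± 0.414 CPM (camera adjusted p = 0.00897, and adjusted p = 0.963 with an estimated correlation). In NN-Astro 6 of 12 myelin genes were lower, 7 adjusted over the list alone (0.00420), and over all nuclei 4 of 15, 5 adjusted over the list alone (0.0221), neither called with an estimated correlation (adjusted p = 0.963). In NN-ODC itself 1 of 15 myelin genes was higher and 1 lower. Oligodendrocyte markers, which share Mbp and Mobp with that list, were lower for 5 of 9 genes in inhibitory neurons (0.0190) and 5 of 7 in NN-Astro (0.00404), again not with an estimated correlation (adjusted p = 0.963). In inhibitory neurons Mbp was not called without DBA library 2 (0.0727), nor Opalin without BL6 library 2 (0.220) or DBA library 3 (0.175). With genes counted in both strains the myelin list was also called lower in excitatory neurons (0.00375) and higher in NN-OPC (0.000976), 2 units where an estimated correlation on all genes gave adjusted p = 0.963. Microglial markers over all nuclei were lower for 7 of 11 genes, 8 adjusted over the list alone, with the complement gene C1qb from 22.5 ± 3.62 to 6.96 ± 2.30 CPM (0.0212). They were called in inhibitory neurons (0.00865), NN-Astro (0.00709) and NN-MGC (0.00288) too, and in no unit with an estimated correlation (adjusted p = 0.963). Over all nuclei C1qc was not called without BL6 library 2 (0.0902) or BL6 library 3 (0.127), nor Tmem119 without BL6 library 3 (0.1003) or DBA library 3 (0.237). The lower mean shares of NN-ODC and NN-MGC nuclei in DBA go with the falls over all nuclei. The NN-MGC share was not lower in every DBA library, at 5.89% in DBA library 2 against 5.77% in BL6 library 2. Endothelial markers over all nuclei were lower for 5 of 9 genes, 7 adjusted over the list alone, with the receptor Tek from 33.5 ± 5.47 to 0.851 ± 0.337 CPM (0.00648, and adjusted p = 0.963 with an estimated correlation). NN-Endo-SMC-Peri, the type highest in the endothelial markers Cldn5 and Flt1, made up 1.21 ± 0.239% of RNA nuclei in BL6 and 0.316 ± 0.244% in DBA. The lower share goes with the list, but its fall is smaller than that of Tek (-5.31 on the log2 scale). Different gene models per strain were not tested for Tek and are not excluded. Without DBA library 3, Ly6c1 (0.0934) and Slco1a4 (0.0861) were not called.

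**Figure D3:**
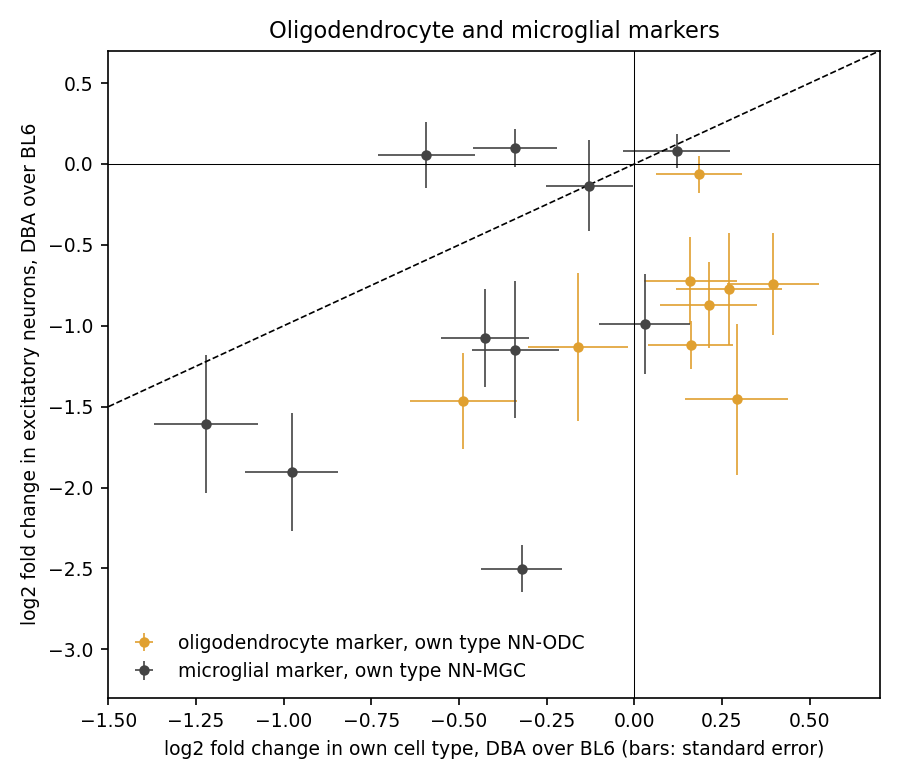
Log2 fold change, DBA over BL6, of oligodendrocyte (yellow) and microglial (dark) markers in excitatory neurons against that in their own cell type, with standard errors from 2 libraries per strain and a diagonal line at equality. Of the 19 markers, 17 lie under the line, lower in excitatory neurons than in their own type, such as Ermn at -1.455 against 0.29, and Csf1r and P2ry12 by less than their standard errors.

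Lists of synaptic genes were called in 1 unit, NN-Endo-VLMC, and in none with an estimated correlation (adjusted p = 0.963). With genes counted in both strains GABA-A receptor subunits were also called lower in NN-ODC (0.0283, and adjusted p = 0.963 on all genes with an estimated correlation). NN-Endo-VLMC held 10, 35, 27 and 18 nuclei in the 4 libraries. Some markers of other cell types stood high there, with Foxp2 at 1504.5 CPM and the astrocyte gene Gja1 at 323 ± 15.7 CPM over the 4 libraries. The astrocyte gene Aqp4 did not, at under 42.8 CPM. Cntnap5b rose there from 23.7 ± 17.6 to 247 ± 130 CPM. RNA of neurons in these nuclei is thus not excluded as the source of the synaptic transcripts. In this type 8 of 11 ionotropic glutamate receptor genes were higher in DBA and none lower, 9 adjusted over the list alone, with Grik2 from 63.8 ± 13.5 to 522 ± 44.8 CPM and Grin2b from 75.6 ± 4.69 to 358 ± 128 CPM (camera adjusted p = 6.17e-08, and adjusted p = 0.963 with an estimated correlation). Potassium channel genes were higher for 6 of 11, 7 adjusted over the list alone, with Kcnip4 from 212 ± 43.6 to 1388 ± 695 CPM (4.05e-05). Without BL6 library 3, Kcnd2, Kcnh7 and Kcnj3 were not called, at adjusted p of 0.0585, 0.0700 and 0.204. GABA-A receptor subunits (2 of 5, 0.00274), presynaptic genes (3 of 14, 0.00199) and postsynaptic density genes (2 of 14, 0.0181) were also higher. Immediate early genes were lower for 4 of 6, 6 adjusted over the list alone, with Nr4a2 from 190.3 ± 37.8 to 9.99 ± 1.53 CPM and Nr4a3 at least 12.6-fold lower (1.67e-06, and adjusted p = 0.963 with an estimated correlation). Nr4a1 was not called without BL6 library 2 (0.103), nor Dusp1 without BL6 library 2 (0.190), DBA library 2 (0.242) or DBA library 3 (0.0523).

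Other fixed lists held single called genes. Of cholesterol synthesis genes 3 of 19 were called in oligodendrocyte precursors, all lower, 3 adjusted over the list alone, with Fdps from 21.7 ± 5.12 to 4.92 ± 0.263 CPM and Nsdhl from 19.3 ± 1.56 to 4.90 ± 1.19 CPM (camera adjusted p = 0.0183, and adjusted p = 0.963 with an estimated correlation), while Fdft1 was not called without BL6 library 2 (0.116) or DBA library 2 (0.125). Among neuropeptides in inhibitory neurons, 4 of 23 were called, 2 each way, but Cartpt not without BL6 library 3 (0.0598) or DBA library 3 (0.114). Vasopressin (Avp) fell from 48.2 ± 8.31 to 10.0 ± 2.03 CPM (-2.24, adjusted p = 7.49e-07, both DBA libraries lower), Npy rose from 45.3 ± 7.07 to 75.0 ± 12.9 CPM and Tac2 from 8.13 ± 0.146 to 14.1 ± 1.27 CPM. In excitatory neurons 4 of 12 genes of MHC class I were called, 3 higher and Tap2 lower (-1.17, adjusted p = 0.0449), with H2-D1 up from 5.94 ± 0.376 to 14.4 ± 2.505 CPM and H2-K1 from 1.23 ± 0.103 to 4.26 ± 0.820 CPM, and the neuromedin B receptor Nmbr rose from 0.623 ± 0.172 to 2.21 ± 0.0262 CPM. Tap2 was not called without BL6 library 2 (0.441), DBA library 2 (0.167) or DBA library 3 (0.121), nor H2-Q7 without BL6 library 2 (0.0994). The interferon gene Xaf1 fell from 3.86 ± 1.26 to 0.690 ± 0.119 CPM there, and Mx1 had counts in DBA alone. The adhesion gene Nlgn3 fell in inhibitory neurons from 36.3 ± 1.38 to 20.2 ± 0.415 CPM, and in NN-Astro the vesicle gene Sv2c went from 8.18 ± 2.12 to 49.2 ± 20.6 CPM. In oligodendrocytes the receptor Grm7 fell from 736 ± 99.8 to 286 ± 9.37 CPM, and in their precursors Gabrb2 rose from 157.5 ± 0.858 to 268 ± 9.93 CPM. In all, 38 of 259 tests of a list in a unit were called, 5 up and 33 down, from 14 of 36 lists, and 0 of them with an estimated correlation (camera, adjusted p = 0.963). On genes counted in both strains 54 were called, 7 up and 47 down. With an estimated correlation the smallest adjusted p of camera was 0.963 for every list, that of the mitochondrial genome included. That setting thus does not tell the lists apart.

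The second comparison asked whether the strain difference in RNA was the same in non-neuronal nuclei and in neurons. Syt10, a synaptotagmin, was at 23.3 ± 1.86 CPM in neurons of BL6 and 21.6 ± 2.21 in those of DBA, was called lower in Exc-Tafa1, from 16.9 ± 3.04 to 6.56 ± 2.16 CPM (log2 -1.36, adjusted p = 0.00594), and rose in non-neuronal nuclei from 5.39 ± 0.732 to 56.1 ± 6.14 CPM. In NN-Astro it rose from 8.21 ± 0.904 to 105 ± 6.69 CPM. Fcho1, an endocytic adaptor, went from 6.21 ± 0.0629 to 31.3 ± 0.876 CPM in non-neuronal nuclei, and from 4.50 ± 0.0666 to 176 ± 5.56 CPM in NN-ODC. Psat1, an enzyme of serine synthesis, was at 2.07 ± 0.231 CPM in neurons of BL6 and 21.1 ± 1.64 in neurons of DBA, against 39.5 ± 8.60 and 30.3 ± 3.87 CPM in non-neuronal nuclei. Nlrp1b, an inflammasome sensor, was at 22.8 ± 0.828 CPM in non-neuronal nuclei of BL6 and 2.18 ± 0.559 in those of DBA, and in NN-MGC at 244 ± 30.5 and 22.4 ± 6.54 CPM, while it was called higher in Exc-Abi3bp (4.11) and Exc-Vwa5b1 (2.68).

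The test of the difference (edgeR interaction, libraries as a block) gave log2 values of 3.60 for Syt10 (adjusted p = 3.79e-07), 2.47 for Fcho1 (1.24e-05), -3.52 for Psat1 (7.48e-06) and -5.59 for Nlrp1b (2.55e-05), in the direction of both DBA libraries. Ifitm10 fell in non-neuronal nuclei from 60.7 ± 7.58 to 9.98 ± 0.868 CPM (interaction -2.78), against 7.62 and 5.69 CPM in neurons of the BL6 libraries and 8.20 and 8.30 CPM in those of DBA, with NN-MGC at 571 ± 20.1 and 88.9 ± 25.3 CPM. Nxpe2 went from 73.6 ± 8.25 to 25.3 ± 1.79 CPM there (-1.54). Rbm20, a splicing factor, was lower in DBA neurons at 8.19 ± 0.464 against 23.1 ± 1.45 CPM, and higher in DBA non-neuronal nuclei at 52.9 ± 4.14 against 31.9 ± 3.92 CPM (2.35). In NN-Astro Rbm20 rose from 49.5 ± 3.36 to 87.1 ± 11.3 CPM. Its mean was lower in DBA in NN-OPC, where the fall was not called. It was also lower in NN-MGC, NN-ODC, NN-VLMC and NN-Endo-VLMC, where counts were too few to test. Arhgap26 was lower in both classes, from 313 ± 8.92 to 37.4 ± 1.08 CPM in neurons and from 164 ± 29.2 to 66.0 ± 2.08 CPM in non-neuronal nuclei (1.88), but was called higher in NN-ODC, from 16.5 ± 1.31 to 50.4 ± 5.58 CPM (log2 1.74, adjusted p = 5.87e-06). Of 23481 genes, 579 were called, 379 higher and 200 lower in the non-neuronal difference, or 65.5% higher, and 44.1% with total counts alone. The count was 308 with DESeq2, 226 with no library block, 43 without DBA library 3, 127 without DBA library 2, 878 without BL6 library 2 and 1610 without BL6 library 3, and in simulated data 23.8% of the calls of this test were false.

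**Figure D4:**
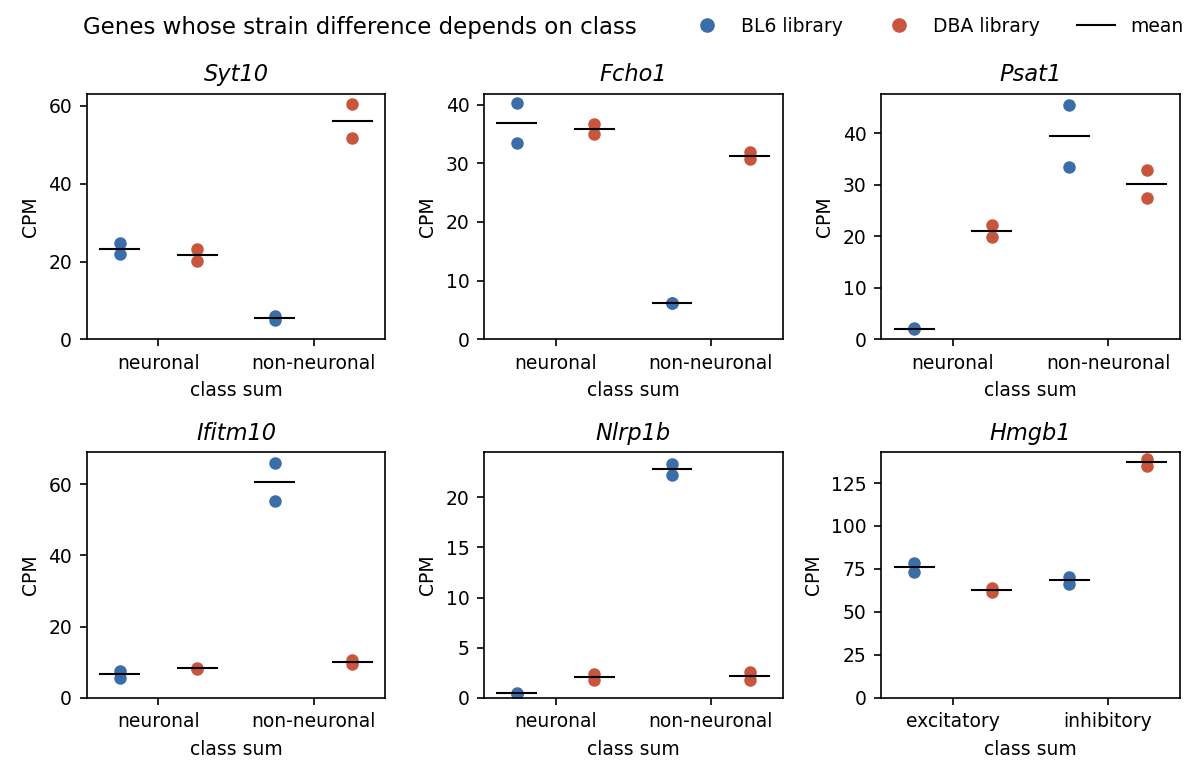
CPM of 6 genes in each library (points) with the mean of the 2 libraries per strain (bars), in neurons and non-neuronal nuclei, or for Hmgb1 in excitatory and inhibitory neurons. Syt10 rises in DBA in non-neuronal nuclei, from 5.39 to 56.1 CPM, and Hmgb1 in inhibitory neurons, from 68.3 to 137 CPM.

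The third comparison set the strain difference in inhibitory neurons against that in excitatory neurons. Hmgb1, a chromatin protein, rose in inhibitory neurons from 68.3 ± 3.19 to 137 ± 2.89 CPM and was at 75.8 ± 3.31 and 62.8 ± 1.59 CPM in excitatory neurons (interaction log2 1.27, adjusted p = 2.18e-05, both DBA libraries). Among inhibitory types it was highest in Inh-Lamp5 of DBA, at 308.5 ± 11.4 CPM against 62.5 ± 5.35 in BL6. Schip1 fell further in inhibitory neurons, from 1018 ± 75.2 to 21.6 ± 3.02 CPM, than in excitatory neurons, from 960.0 ± 77.2 to 41.1 ± 9.98 CPM (-0.995). The phosphatase gene Ptprt was at 671 ± 24.4 and 806 ± 52.9 CPM in inhibitory and 263 ± 7.96 and 206 ± 12.4 CPM in excitatory neurons (0.62). Lmntd1 (1.66), Cntnap5b (0.50), Synpo2 (-1.49), Banf2 (-3.83) and the potassium channel subunit Kcnmb2 (-0.59) were also called. Without DBA library 3 those 5 ended at adjusted p of 0.0580, 0.0776, 0.0799, 0.101 and 0.0726, and without BL6 library 2 Lmntd1, Cntnap5b, Synpo2 and Kcnmb2 ended at 0.0530, 0.0873, 0.136 and 0.110. Of 22575 genes, 33 were called, 17 higher and 16 lower, against 62 without BL6 library 2, 67 without BL6 library 3, 58 without DBA library 2, 26 without DBA library 3, 15 with DESeq2 and 1 with no library block, and 15.6% of calls were false in simulated data.

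The fourth comparison asked which peaks differed in accessibility between the strains. A peak inside Sfi1 (chromosome 11, 3192711 to 3193843) rose from 33.2 ± 1.01 to 371 ± 30.04 CPM over all nuclei and in all 16 cell types tested. Peaks inside Pisd-ps2 (chromosome 17, 3081299 to 3083318) and Gm40371 (chromosome 6, 47647770 to 47651583) rose from 13.7 ± 0.371 to 85.9 ± 1.25 CPM and from 43.3 ± 1.91 to 274 ± 9.02 CPM, each in 16 types. Copies of Sfi1 and Pisd stand elsewhere in the genome, so the values of their peaks are uncertain, as in RNA. A peak between genes on chromosome 6 (3200915 to 3201604) fell from 27.4 ± 2.13 to 0.0902 ± 0.128 CPM and was called in 15 types. A peak on chromosome 2 (98666180 to 98667320) fell from 199 ± 31.8 to 76.5 ± 7.16 CPM. Peaks at the ends of Stab2 (3.56 ± 0.209 and 8.15 ± 1.95 CPM) and Sfi1 (0.556 ± 0.0536 and 21.6 ± 1.13 CPM) were higher in DBA, as was that of Cox16 (2.74 ± 0.0475 and 4.26 ± 0.354 CPM), whose RNA was lower. Peaks on unplaced contigs, 47 in number, held 33252 and 36039 counts in the BL6 libraries and 0 in DBA. These counts argue against the same mapping or counting of both strains on the contigs. Such a difference was not tested at other peaks and is not excluded there, so a called peak is not known to differ in accessibility.

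Over all nuclei 17470 of 271420 peaks were called by edgeR, 8706 higher and 8764 lower in DBA, and summed over the 16 types 25356, 12701 higher and 12655 lower, from 12 in NN-OPC to 7883 in Exc-Tafa1. The even balance depended on the scaling. With total counts alone 6397 were higher and 8883 lower over all nuclei, and 11049 and 13441 over the types. Of 14838 peaks called in any type, 4259 were called in 2 or more, 98.8% of them in 1 direction. The sum over types was 13937 without BL6 library 2 and 13111 without BL6 library 3, the count over all nuclei 8779 and 9194, and DESeq2 called 7156 and 7142. The strain difference in accessibility did not differ detectably between non-neuronal nuclei and neurons at this depth. Of 270843 peaks, 0 were called by edgeR and 0 by DESeq2, and 6234 had an unadjusted p under 0.05. In simulated data this test recovered 1.52% of peaks changed 4-fold.

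The last comparison asked whether RNA and accessibility near the gene's ends differed in the same direction. Fggy, a carbohydrate kinase gene chosen after its values were seen, fell from 54.7 ± 4.24 to 2.22 ± 0.0343 CPM in RNA, and its peak on chromosome 4 (95556818 to 95558818) was lower in the same 12 cell types. Hjurp, a centromere chaperone, was lower in RNA and in its peak in 10 types, Gon4l in 7 and the meiotic gene Rec8 in 6, and Alad was higher in both in 9 types and the complement regulator Cd59a in 6. These genes too were picked from the values. Over 688 pairs of a called gene and a called peak within 2 kb in the same cell type, 73.5% went in the same direction (95% exact interval 70.1 to 76.8), 309 both higher and 197 both lower (odds ratio 8.51, Fisher's exact test, two-sided p = 2.72e-36). In 98 of the 688 pairs the gene was not counted in both strains, and the test on genes counted in both gave 74.1% of 590 pairs (70.3 to 77.6). Over all nuclei 376 pairs gave 66.5% (61.5 to 71.2; Fisher's exact p = 4.94e-10). Etnk2 went in opposite directions in 7 types, and Sycp3 and Zfp951 in 6 each. Genes recur across cell types and are not independent replicates, so these p-values are too small. A strain difference in mapping or counting that touched both assays is not excluded as a source of shared direction.

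**Figure D5:**
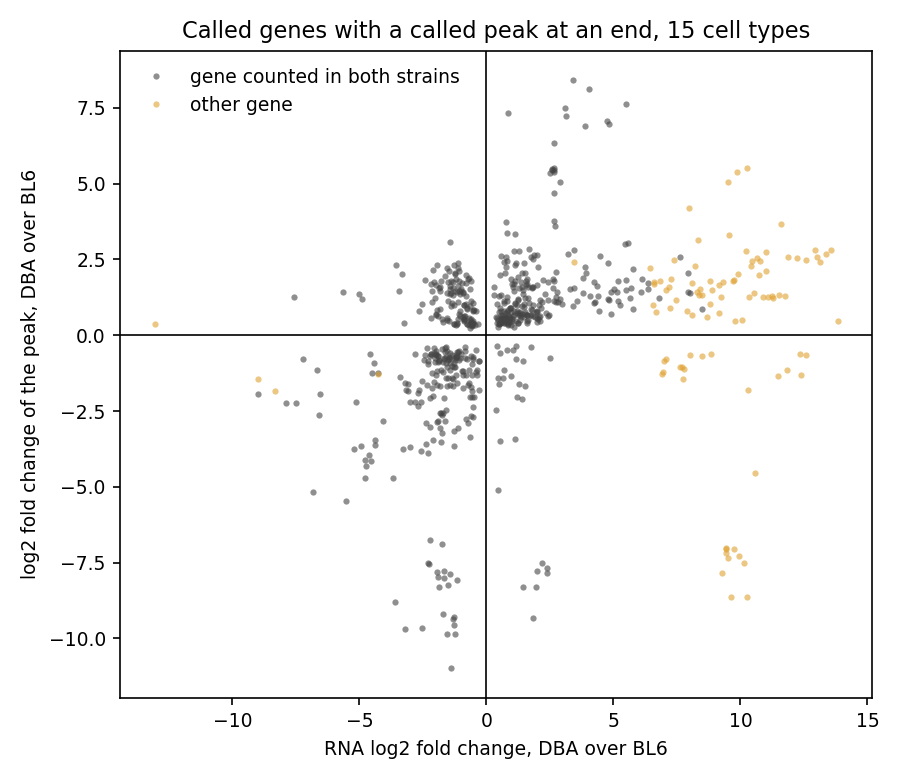
Log2 fold change of RNA against that of a called peak within 2 kb of the gene's ends for 688 pairs in matching cell types, dark where the gene was counted in both strains and yellow otherwise. Points in the lower left and upper right corners, 73.5% of all, have the same direction in both assays.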

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

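The test of renamed pairs and the 4 tests of mitochondrial and glial transcripts were chosen after those results were seen, and the other tests in this part before.

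A test of the interaction itself called a strain difference in RNA that differed between non-neuronal nuclei and neurons for 579 genes, and between inhibitory and excitatory neurons for 33. DESeq2 called 308 and 15 and a fit with no library block 226 and 1, and in simulated data 23.8% and 15.6% of calls were false. On the log2 scale, the non-neuronal difference exceeded the neuronal one by 3.60 for Syt10, 2.35 for Rbm20, 2.47 for Fcho1 and 1.88 for Arhgap26, and the interaction was -3.52 for Psat1, -2.78 for Ifitm10, -5.59 for Nlrp1b and -1.54 for Nxpe2. The inhibitory difference exceeded the excitatory one by 1.27 for Hmgb1, 1.66 for Lmntd1, 0.62 for Ptprt and 0.50 for Cntnap5b, and the interaction was -0.995 for Schip1, -1.49 for Synpo2, -3.83 for Banf2 and -0.59 for Kcnmb2. The first count was 43 without DBA library 3, 127 without DBA library 2, 878 without BL6 library 2 and 1610 without BL6 library 3, and the second was 62, 67, 58 and 26 without BL6 library 2, BL6 library 3, DBA library 2 and DBA library 3. Lmntd1, Cntnap5b, Synpo2, Banf2 and Kcnmb2 were not called without DBA library 3, at adjusted p of 0.0580, 0.0776, 0.0799, 0.101 and 0.0726. Without BL6 library 2, Lmntd1, Cntnap5b, Synpo2 and Kcnmb2 were not called either, at 0.0530, 0.0873, 0.136 and 0.110.

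Genes counted in 1 strain alone, such as Marchf1 in DBA and March1 in BL6, may come from counting the strains against different gene sets. Of 68 pairs of older and newer names, 88.2% lay within 1.5-fold once joined, as that explanation needs for these pairs. Pairs with few counts under either name were left out, so a gene silent in 1 strain could not enter this test. The share therefore cannot decide for genes without a second name. That genes counted in 1 strain alone are silent or absent in the other strain was tested by accessibility. Of 107 of them, 4.67% (5 genes, 95% exact interval 1.53 to 10.6) had a peak at least 2-fold different in the direction of the RNA. The interval reaches past the 10% set beforehand as the bound against that explanation, so it stays open for part of the genes. Genes that only carry another name in the other strain were kept among the 107. They need no such peak and dilute the share, so the test cannot decide for the remaining genes. The 5 genes are Erdr1, Gm10060, Pisd-ps1, Pisd-ps2 and Tmem181c-ps, and reads shared between copies of Pisd were not tested.

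The 71 genes counted in both strains and called in 15 or more cell types, such as Stab2 and Cox16, could reflect strain differences in regulatory DNA or different gene models. Of the 57 with a peak near an end, 19.3% had a called peak, against 6.74% of 16535 uncalled genes (Fisher's exact test, two-sided p = 0.00137), as a difference in regulatory DNA needs. This share takes called peaks of either direction. Peaks on unplaced contigs had 0 counts in DBA, which argues against the same mapping or counting of ATAC reads of both strains on these contigs. At the peaks of these genes a strain difference in mapping was not tested and is not excluded. The share alone therefore cannot decide for regulatory DNA. Of 11 with a called peak, 63.6% went the same way as the RNA (7 genes, 95% exact interval 30.8 to 89.1). That interval holds 50%, the value set beforehand for different gene models, and also reaches above 60%, the bound against them, and reading it as undecided was decided after the value was seen. For these 11 genes the explanations cannot be told apart, because 11 is too few.

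Mitochondrial mRNAs and glial markers were both lower in DBA in nuclei that should hold little of either, and free RNA in BL6 droplets may account for the oligodendrocyte part. Over the 9 oligodendrocyte markers the log2 fold change in excitatory neurons minus that in NN-ODC had a median of -1.04 and was negative in 9, as free RNA needs, though Mbp fell in neurons by less than its SE (-0.06). Microglial markers had a range of 2.600 on the log2 scale in excitatory neurons. C1qb was at -1.90 there, and Csf1r (-0.13), Cx3cr1 (0.10), P2ry12 (0.08) and Selplg (0.06) lay within their SE of 0. Free RNA as the whole cause would need a narrow range only if all neuronal counts of these markers were free RNA. That need not hold, since P2ry12 was at 202 CPM in Exc-Vwa5b1, against 872 CPM in NN-MGC. The range therefore cannot decide on free RNA for the microglial markers. Of the 19 markers 17 were lower in neurons than in their own type, Csf1r and P2ry12 by less than their SE. Different gene sets would move both cell types alike only if the counts in both came from the same transcripts. That was not tested, so this count cannot exclude different gene sets for the glial markers. For mitochondrial mRNAs free RNA as the whole cause is argued against by their range of 9.72 on the log2 scale, from mt-Co2 (-10.66) to mt-Atp8 (-0.94). Different gene sets for the mitochondrial genome, where mt-Nd3 was counted in BL6 alone and mt-Rnr1 and mt-Rnr2 in DBA alone, and a strain difference in these transcripts stay open and were not tested.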

How the results depend on the processing

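Leaving out a library compares 2 libraries with 1, which is assumed to vary like the others, and the settings with genes counted in both strains and with the crossed block were chosen after the data were seen. Without the filter on low counts, RNA calls summed over types were 46579, and 1117 and 145 genes were called in the non-neuronal and inhibitory interactions, where more genes were tested. With genes counted in both strains, fewer genes were tested, and RNA calls were 12183 over types, 1033 over all nuclei, and 1754, 1583 and 1416 in excitatory, inhibitory and non-neuronal sums. Columns thinned to equal depth held fewer counts and gave 18761. DESeq2 called 308 and 15 genes in the 2 RNA interactions, and 7156 peaks over types and 7142 over all nuclei. With no library block the interactions had 226 and 1 genes and 2 peaks, and peaks changed beyond 1.5-fold were 10351, a stricter test by construction. With an estimated correlation 0 lists were called, a setting that could hardly call any with 2 libraries per strain. Leaving out a library gave 43 to 1610 and 26 to 67 genes in the 2 RNA interactions, 2512 to 4624 in non-neuronal nuclei, 13111 to 24894 peaks over types, 8779 to 19857 over all nuclei and 0 to 5 in the ATAC interaction. Where no construction is named, the cause was not tested. RNA calls over types ranged from 22683 to 33083 without a library. RNA and ATAC went the same way in 70.2% and 61.5% of pairs (cell types and all nuclei) within 10 kb, 74.1% and 68.5% with genes counted in both strains, and 70.6% to 79.8% and 64.9% to 66.4% without a library.

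Among named genes, signs turned for 3 that were not called. Glo1 was at -0.0107 with total counts alone and from -0.31 to 0.31 without a library, Fscn2 from -0.62 to 0.14 and Mpdz from -0.21 to 0.10, and the cause was not tested. Over all alternatives, 2010 values of named genes and peaks kept direction and side of the threshold, 233 lost the call, 11 gained it and 6 turned sign.

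With the library number as a replicate block, Glo1 was at -0.000338, RNA calls were 28865 over types and 5263 over all nuclei, peaks 28570 and 15531, and lists 34. The numbers are not known to pair libraries, and correlations of same-numbered libraries across genes ran from -0.28 to 0.07 in RNA, 4 of 21 under -0.1, and from -0.05 to 0.02 in ATAC. The crossed block gave 29616, 7597, 27855 and 19567 calls. Depth limits the ATAC interaction, where 1.52% of simulated 4-fold changes were recovered.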

Other observations

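Apart from the immediate early genes at its end, genes of this paragraph belong to fixed lists that were called in no unit by camera, and they were picked for the text by the rule for named genes. Zfp genes in excitatory neurons were called for 59 of 331, 27 higher and 32 lower in DBA, 49 adjusted over the list alone. Zfp91 fell there from 44.9 ± 3.84 to 2.87 ± 0.225 CPM and Zfp949 rose from 33.5 ± 0.754 to 83.5 ± 0.562 CPM. Protocadherins, adhesion molecules with clustered genes, were called for 9 of 57 over all nuclei, 5 higher and 4 lower (0.447), with Pcdha8 higher by 1.79 on the log2 scale, at 2.05 ± 0.258 CPM in DBA. The ependymal marker Dnah6 rose from 3.12 ± 1.18 to 14.6 ± 0.6005 CPM over all nuclei, without its list (0.779). The clock gene Hlf fell in inhibitory neurons from 32.1 ± 6.92 to 19.9 ± 1.57 CPM (list 0.0858). The fibroblast gene Col1a1 fell in excitatory neurons from 4.17 ± 1.86 to 0.527 ± 0.350 CPM (list 0.438). Immediate early genes were called lower as a list in inhibitory neurons, with 2 of 21 called and 1 adjusted over the list alone (camera adjusted p = 0.0379, and adjusted p = 0.963 with an estimated correlation).

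The other lists called in no unit had smallest adjusted p values of 0.0740 for medium spiny neuron markers, 0.0863 for astrocyte markers, 0.213 for neuropeptides, 0.233 for excitatory markers and 0.294 for oligodendrocyte precursor markers. The value was 0.303 for monoamine receptors and for pericyte and mural markers, 0.422 for choroid plexus markers, 0.447 for metabotropic glutamate receptors and for interferon response, and 0.459 for MHC class I. It was 0.464 for the DNA methylation machinery, 0.598 for neuropeptide and opioid receptors, 0.605 for inhibitory markers, 0.633 for hypothalamic markers and 0.734 for hippocampal granule markers. With genes counted in both strains, astrocyte markers were called lower in NN-MGC (0.0283) and interferon response over all nuclei (0.0146), where an estimated correlation on all genes gave adjusted p = 0.963 for both.

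The choroid plexus transcript Ttr had 11999 counts in BL6 library 2 and 55, 12 and 25 in the other RNA libraries. Gm42418, which overlaps ribosomal RNA, was at 3729 and 3795 CPM in BL6 and had no counts in DBA, while mt-Rnr1 and mt-Rnr2 together were at 1396 and 3572 CPM in DBA and had no counts in BL6. Of the genes counted in DBA alone, 85.8% had provisional symbols and 46.2% were found in RefSeq, against 85.8% of genes counted in both strains. The receptor gene Glp1r had 52 and 22 counts in BL6 and 198 and 1166 in DBA, and it was higher in RNA and in its peak in 5 cell types. It was chosen after its values were seen. Prkcd, a marker of central amygdala neurons, was highest in NN-MGC at 233 ± 52.4 CPM over the 4 libraries.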
